A study of Homo sapiens with 8 samples.

How the data were processed

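The samples were 8 arrays of a single cell line, 4 labelled shControl and 4 labelled shZNF395, grouped and numbered by the sample labels. Per the labels' protocols, the cells were transduced with lentiviral hairpins and selected, and total RNA was extracted at 48 h; the labels call the time post-transfection, and whether the replicate numbers stand for different hairpins is not given in the sources used here. RNA was biotin-labelled for Illumina Expression BeadChips, per the labels' protocols.

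The deposited non-normalized table holds, per the file headers, a signal intensity and a detection p-value for each of 47323 probes on each array. The deposited series matrix holds normalized intensity values on a linear scale for the same probes, and the submitters' processing notes name lumi without a version. The authors' deposited table of fold changes holds 1 value for each of 39747 transcript entries and no value per array, so it was not used for any test. By a fit to the values, its scale follows an inverse hyperbolic sine of the series matrix values, close to log2 at high signal (slope 1.042) and compressed at low signal.

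The signal tables name probes and the fold-change table names transcripts, and neither pairs these names, so the pairing was recovered from the values. The difference of group means of the transformed series matrix values was computed for each probe and matched to the deposited fold changes within 1e-09. The starting values of the 3 transform parameters were found by trial, using a few probe and transcript pairs presumed from general knowledge of the array; they were then refitted on the deposited values alone. The match found 1 probe for 33125 entries (83.3%), against 0.0419% after the values were shifted, which is the share chance gives. A further 517 entries matched the mean of 2 probes. A first pass of that search accepted 245 entries, against 0.25 after a shift. Such entries can be resolved only where the change is large, so their genes entered the rule for named genes, with p-values adjusted over all detected probes, and no count or gene list test. Entries were named through a RefSeq table of GRCh38.p14, used for names only: 22411 entries had 1 symbol, and 47.2% of the detected probes had none. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

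The raw signals were processed with limma 3.58.1 in R 4.3.3: normexp background correction with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes were kept when detection p was under 0.01 on at least 4 of the 8 arrays, and each gene was read by its brightest kept probe over all 8 arrays. Of 423 genes with over 1 kept probe, 252 were called. Every other kept probe passed in the same direction for 154 of them, and for 8 another probe passed in the opposite direction. Differences are shZNF395 minus shControl from lmFit and eBayes, two-sided, with Benjamini-Hochberg adjusted p under 0.05 and no fold limit. Where a probe was below detection on every array of a group, the fold is a lower bound: the brighter group's mean against the mean of, per array, the higher of the dim probe's own value and the lowest detected signal. This applied to 133 called genes.

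Before the data were examined, 34 gene lists with 750 entries were fixed, and those with at least 5 measured members, 29 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists. 14 measured genes stand on over 1 list. Camera with an estimated correlation was the alternative; of 10 lists past the test, 6 also pass with it. The genes named are ZNF395, TARBP2 and APP; the 10 largest rises and 10 largest falls with adjusted p under 0.05, groups that do not overlap and detection on all 4 arrays of the higher group, leaving out symbols that are only locus numbers; and up to 3 members with the smallest p of each list with a called member. Genes that met this rule but are withheld are not reported here.

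The fit was tested on simulated data for shZNF395 against shControl over 7739 genes, with 50 genes changed at each of 4 sizes. It recovered 48% of the genes changed by 0.3 on the log2 scale, 78% at 0.5, 98% at 1 and 100% at 2, with 9 false calls among 7539 unchanged genes. The simulated noise was independent between genes, rises and falls were balanced, and a far smaller share of genes changed than was called in the real data. These recovery rates may therefore differ from those of the real fit. The simulation also does not test the normalization where most genes change. Alternatives covered background correction, normalization, the series matrix values, the detection filter, the probe of a gene, thresholds, moderation, array weights, the replicate number as a block and each array left out. Slide could not be used as a block because the column names give none, and ZNF395 has only 1 named probe. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the pairing, and matplotlib 3.10.9 for the figures.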

Results

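Gene expression was measured on Illumina BeadChips in MDA-LM2-shTARBP2 cells. MDA-LM2 is a lung-metastatic derivative of the human breast cancer line MDA-MB-231, and in this version TARBP2, a double-stranded RNA-binding partner of Dicer, is itself targeted by a hairpin. Total RNA from 4 samples carrying a control hairpin (shControl) was set against total RNA from 4 samples carrying a hairpin against the zinc finger transcription factor ZNF395 (shZNF395), all taken at 48 h. The series' design text calls the controls mock-transfected, while the sample labels call them shControl. The median raw signal was between 53.2 and 57.1 per array, and between 16476 and 17406 of 47323 probes were detected on an array, with detection p under 0.01. No pair of arrays was identical. The lowest correlation between arrays of a group (r = 0.9931, across genes) was above the highest between groups (r = 0.9691). The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical, and the 4 arrays per group limit the precision.

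The comparison asks what follows in the transcriptome when ZNF395 is lowered in these cells. ZNF395 itself fell by 0.80 on the log2 scale (SE 0.076, limma adjusted p = 4.8e-06), to 57.3% of the control level, from a mean log2 intensity of 9.89 ± 0.12 (SD, n = 4) to 9.08 ± 0.096 (SD, n = 4). The highest shZNF395 value, 9.22, lay below the lowest shControl value, 9.80. It was read by a single named probe, ILMN_1772876. TARBP2 was slightly higher in shZNF395, by 0.21 (SE 0.066, adjusted p = 0.015) on its brighter probe, while its other detected probe gave a log2 change of 0.06 and did not pass the test (adjusted p = 0.589). APP, the amyloid precursor protein gene, rose by 1.14 (SE 0.098, adjusted p = 2.35e-06) on a dim probe, from 5.55 to 6.69. The authors' deposited table, whose scale is compressed at low signal, gives 0.47 for the entry matched to that probe and 0.12 for another APP entry, which was not matched to a single probe.

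Most tested genes differed between the groups, and the largest changes were rises. IL1B and IL1A, which encode the interleukin-1 cytokines, rose 10.2-fold and 9.39-fold, and MMP3, a matrix metalloproteinase, rose 10.1-fold. KISS1, a metastasis suppressor gene, and TXNIP, an inhibitor of thioredoxin, were among the genes that fell furthest, with log2 changes of -2.03 and -1.95. Of 7739 genes tested with limma, 2381 were higher and 2223 lower in shZNF395 at an adjusted p under 0.05, together 59.5%. Over all 17184 detected probes, with or without a gene name, the balance turned, with 4356 higher and 5156 lower. Most changes were small: the median absolute log2 change of the 4604 called genes was 0.42, against a median residual SD of 0.11 after limma's moderation. With genes below detection in a whole group set at their lower bound, 288 genes were higher and 44 lower by at least 2-fold, and 30 higher and 1 lower by at least 4-fold.

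**Figure D1:**
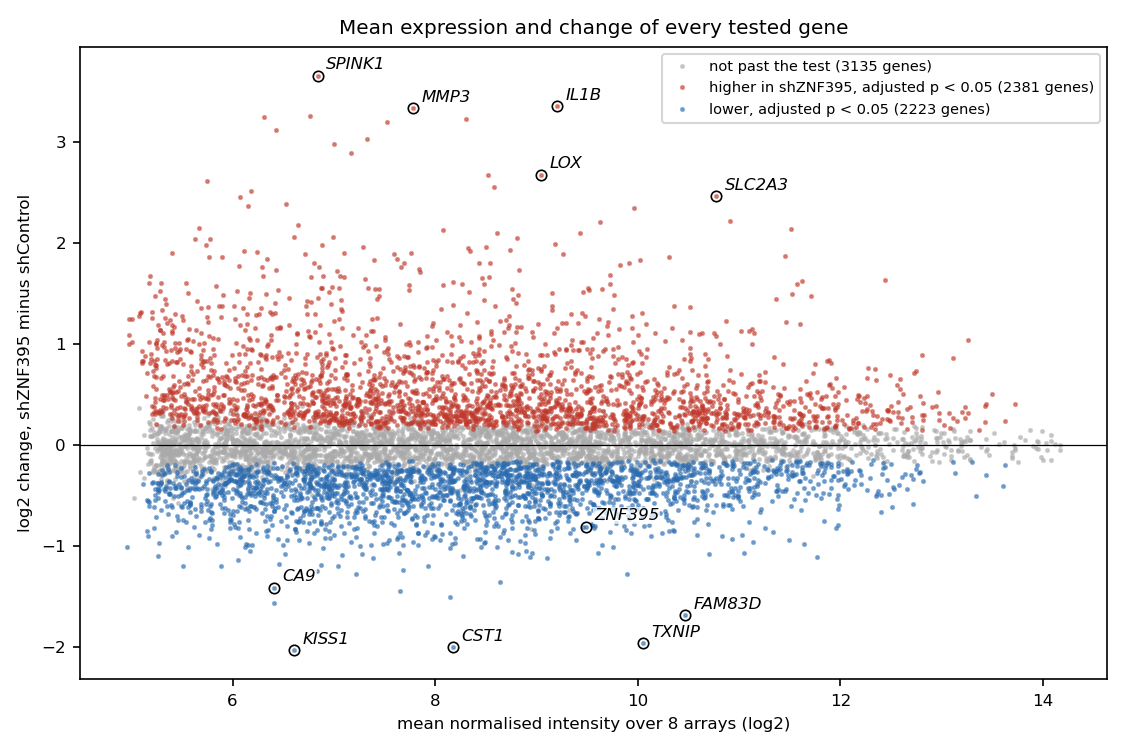
Each point is a tested gene, with its mean log2 intensity over the 8 arrays on the horizontal axis and its log2 change, shZNF395 minus shControl, on the vertical axis, coloured by limma's call at an adjusted p under 0.05. 2381 genes were higher and 2223 lower, and the upper part of the plot reaches further from 0 than the lower part; genes below detection in a group are drawn at their fitted value.

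SERPINB2, a serine protease inhibitor gene, rose by 4.06 on the log2 scale (SE 0.084, adjusted p = 3.51e-10), and its other detected probe gave 3.54. SPINK1, a trypsin inhibitor, rose by 3.66 and the iron-scavenging protein gene LCN2 by 3.26, each with a probe detected on only 1 of 4 control arrays. AKR1C2, an aldo-keto reductase, rose by 3.20 (SE 0.124). Whether its probe also reads the related AKR1C genes was not tested. SPP1 (osteopontin), the complement protease gene C1S and the beta-defensin gene DEFB103A, which has a near-identical copy, were below detection on all 4 control arrays. On the probes used they were at least 6.44-fold, 6.68-fold and 7.23-fold higher in shZNF395. The other detected probe of SPP1 gave a log2 change of 2.45, below the bound of 2.69 on the probe used. That of DEFB103A gave 3.15. Among the falls, CST1, which encodes a cystatin, had a log2 change of -1.99 (SE 0.063), the actin-binding gene TAGLN of -1.84 (SE 0.071) and FAM83D of -1.68 (SE 0.054). The invariant chain gene CD74 was 2.83-fold lower. CABLES2 had a log2 change of -1.56, the small nucleolar RNA gene SNORD31 of -1.44, ETNK1 of -1.42 and CA9, a carbonic anhydrase, of -1.41. These last 5 genes each had a limma adjusted p of at most 5.17e-06.

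**Figure D2:**
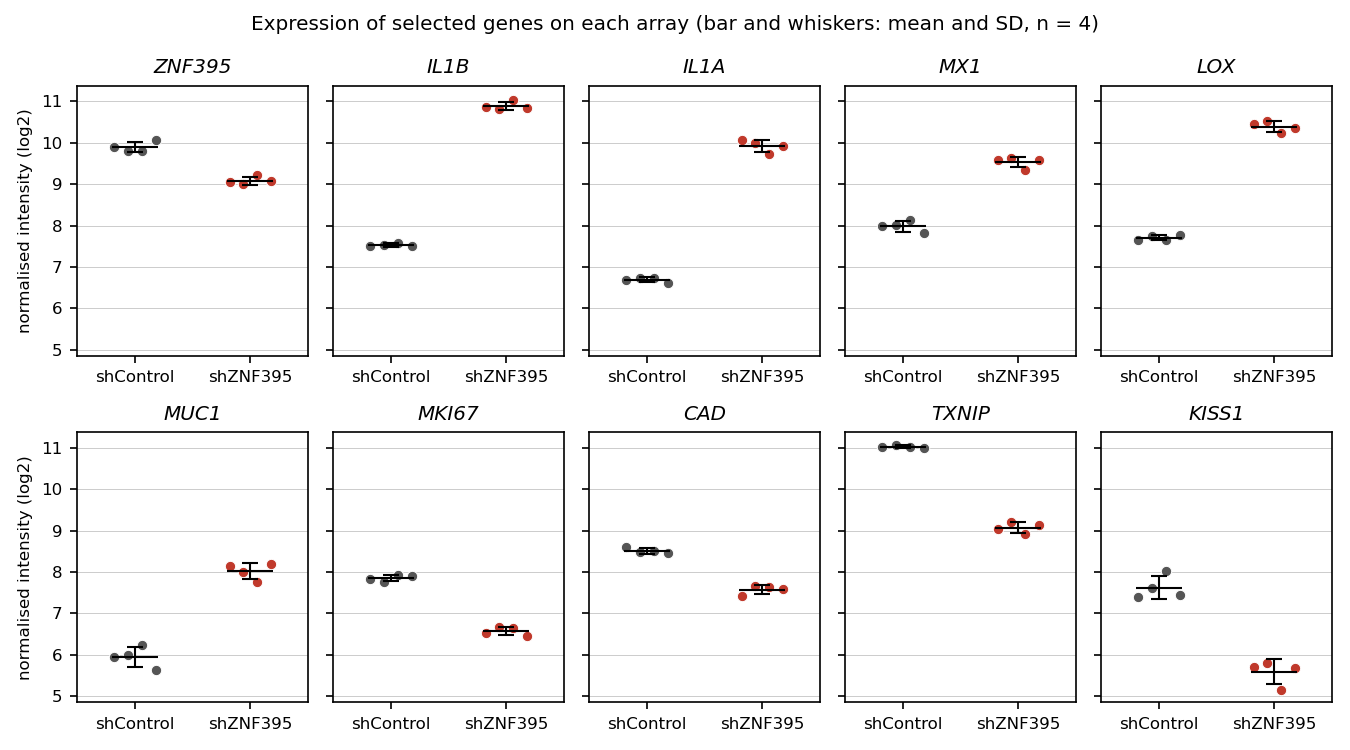
Each point is the normalised log2 intensity of a gene on an array, with shControl in grey and shZNF395 in red, and the bar and whiskers give the mean and SD of 4 arrays. For each of the 10 genes the values of the groups do not overlap; ZNF395 fell from a mean of 9.89 to 9.08 while IL1B rose from 7.53 to 10.88.

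Cytokine, chemokine and feedback genes induced by NF-kappaB rose together. Of 20 measured members of this list, 17 were higher, 2 lower and 1 did not pass, with a median log2 change of 0.78 (camera adjusted p = 1.18e-06). IL1B rose by 3.36 and IL1A by 3.23, and the chemokine gene CCL20, below detection on all control arrays, was at least 4.57-fold higher. Interferon-stimulated genes rose as well: 28 of 33 were higher and 2 lower, with a median log2 change of 0.81 (camera adjusted p = 2.56e-08). ISG20, an exonuclease, rose by 1.79, the antiviral GTPase gene MX1 by 1.55 and IRF9, a subunit of the interferon-activated ISGF3 complex, by 1.16. In the authors' deposited table, over all entries whether detected or not, the median was 0.52 for the NF-kappaB list and 0.27 for the interferon list. The leukocyte marker CD14 rose with these groups by 1.45, and was the called gene of 2 measured leukocyte markers. All 3 measured endothelial markers were higher too, namely ESAM (0.86), ROBO4 (0.49) and PECAM1 (0.36). The PECAM1 call was lost without shControl 1, 3 or 4 or shZNF395 3 or 4, with adjusted p from 0.061 to 0.0913.

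Proliferation genes fell. Of 28 measured genes of G2 and mitosis, 26 were lower and 0 higher, with a median log2 change of -0.52 (camera adjusted p = 2.56e-08). MKI67, which encodes the proliferation antigen Ki-67, fell by 1.27, cyclin A2 (CCNA2) by 0.86 and the kinetochore gene CENPF by 0.73. Of 29 replication genes, 26 were lower and 0 higher, with a median of -0.48 (camera adjusted p = 6.54e-08). Examples are CDC45 (-0.63) and GINS2 (-0.59), both parts of the replicative helicase. Ribosome biogenesis genes and MYC targets fell with them, 13 of 15 lower and 0 higher, with a median of -0.48 (camera adjusted p = 8.32e-06). CAD, which starts pyrimidine synthesis, fell by 0.93, RRP12 by 0.75 and RRS1 by 0.68.

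A list of genes linked to lung metastasis of MDA-MB-231 derivatives rose, with 12 of 15 measured genes higher and 1 lower. Its median log2 change was 0.83, or 0.72 with a gene below detection at its bound (camera adjusted p = 0.000179), against 0.24 over all entries of the authors' table. KYNU, a kynurenine pathway enzyme, rose by 2.35, the collagenase MMP1 by 2.14 and the receptor IL13RA2 by 1.87. The 6 lists named to this point also pass with an estimated correlation between genes, at adjusted p from 0.0182 to 0.0432.

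Lysosomal and autophagy genes were higher in 16 of 19 cases and lower in 1, with a median of 0.70 (camera adjusted p = 1.91e-06). This call is lost with an estimated correlation (adjusted p = 0.0514). The autophagy gene GABARAPL1 rose by 1.96, the protease cathepsin L (CTSL) by 1.63 and the cholesterol transporter NPC1 by 1.16. The other detected probes of CTSL gave 1.01 and 1.75. NRF2 targets were higher in 9 of 12 cases and lower in 1, with a median of 0.66 (camera adjusted p = 0.00116, and adjusted p = 0.0514 with an estimated correlation). They included AKR1C3 (1.60) and the ferritin gene FTH1 (2.22), whose sequence is shared with pseudogenes. Epithelial genes were higher in 4 of 6 cases with none lower, at a median of 1.12 (camera adjusted p = 0.0119, and adjusted p = 0.244 with an estimated correlation). The mucin MUC1 rose by 2.07 on its brighter probe and by 1.43 on its other detected probe. CLDN7 (a tight junction protein) rose by 1.68 and keratin 8 (KRT8) by 0.90. Over all entries of the authors' table the median was 0.28 for the NRF2 list and 0.06 for the epithelial list. Of 5 luminal breast markers 3 were higher, but that list did not pass (camera adjusted p = 0.121). Among them were KRT8 and KRT19 (1.35), which also stand on the epithelial list, so the lists are not independent.

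Hypoxia genes split. Of 23 measured, 12 were higher and 4 lower, at a median of 0.31 (camera adjusted p = 0.0241, and adjusted p = 0.0864 with an estimated correlation). The collagen cross-linking enzyme gene LOX rose by 2.68 and the glucose transporter gene SLC2A3 by 2.47, whereas CA9 fell by 1.41. The median over all entries of the authors' table was 0.04.

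**Figure D3:**
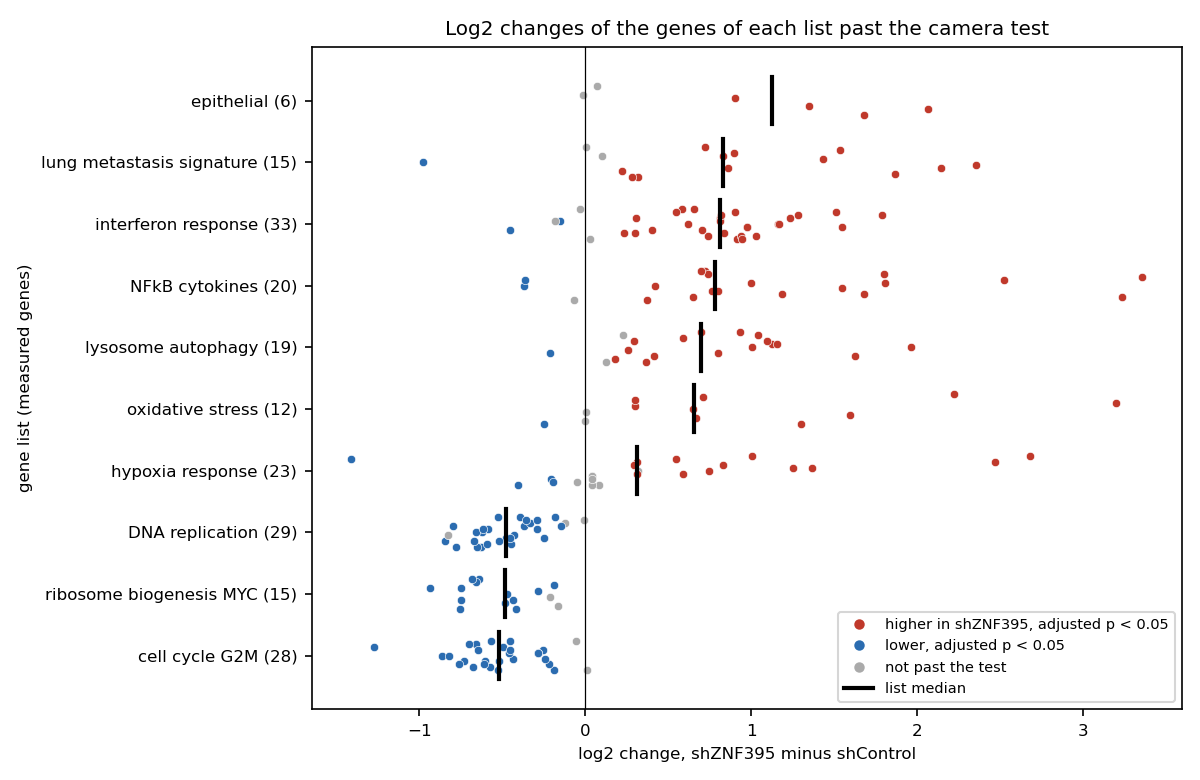
Each point is a gene of a list that passed the camera test, with its log2 change, shZNF395 minus shControl, on the horizontal axis, and black bars mark list medians; points are coloured by limma's call. The medians run from -0.52 for G2 and mitosis genes to 1.12 for epithelial genes, and the hypoxia list holds strong changes on both sides of 0.

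The other 19 lists with at least 5 measured members did not pass. Histone genes went both ways, with 4 of 9 higher and 4 lower (camera adjusted p = 0.532): H2BC21 rose by 1.67 and H1-2 by 0.96, and H2AC6, below detection on all control arrays, was at least 3.24-fold higher. Of 13 p53 targets, 6 were higher and 2 lower (adjusted p = 0.284), and the cyclin-dependent kinase inhibitor gene CDKN1A rose by 1.22. TP53I3 rose by 1.44 on its brighter probe and by 0.27 on the other. Of 17 immediate-early genes 8 were higher and 5 lower (adjusted p = 0.505), with JUNB at 0.90 and KLF2 at -0.63. Of 24 genes of the integrated stress response 9 were higher and 8 lower (adjusted p = 0.944), with DDIT3 at 0.95 and SLC7A1 at -0.82. Its median (-0.04) and its mean (0.08) differ in sign, as do those of the TGF-beta targets (-0.01 and 0.00), of which 1 of 7 was higher and 2 lower (adjusted p = 0.863). Of 17 genes of the unfolded protein response 7 were higher and 3 lower (adjusted p = 0.532), with the chaperone gene HSPA5 at 0.71 and CRELD2 at -0.74.

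Of 27 matrix genes 12 were higher and 6 lower (adjusted p = 0.41), with PLAT, the tissue plasminogen activator gene, at 1.56 and COL6A3 at -1.35. Of 7 mesenchymal genes 3 were higher and 1 lower (adjusted p = 0.505), with ITGA5 at 1.03 and ZEB1 at -0.25. Of 13 YAP targets 3 were higher and 3 lower (adjusted p = 0.41), with FJX1 at -0.49. In metabolism, 8 of 18 cholesterol genes were higher and 3 lower (adjusted p = 0.163), with SC5D at 1.24. Fatty acid genes counted 2 higher and 5 lower of 12 (adjusted p = 0.502), with ME1 at 0.67 and FASN at -0.43. Of 9 glycolysis genes 4 were higher and 1 lower (adjusted p = 0.556), with PFKL at -0.44. Of 33 respiratory chain genes 14 were higher and 5 lower (adjusted p = 0.456), with COX5B at 0.64 and COX8A at -0.39. Of 28 ribosomal protein genes 8 were lower and 0 higher (adjusted p = 0.0859), with RPS2 at -0.58. Of 10 heat shock genes 2 were higher and 3 lower (adjusted p = 0.556), with HSPB1 at 0.75. Of 5 metallothionein genes 3 were lower and 0 higher (adjusted p = 0.121), with MT1G at -0.33. Of 7 genes of the APP family and its secretases 2 were higher and 4 lower (adjusted p = 0.532), with PSEN2 at 0.48 and BACE1 at -0.65. The 10 measured genes around TARBP2 and ZNF395 include ZNF395 itself, the hairpin's target, among the lower genes and APP among the higher. Of these 10 genes 3 were higher and 4 lower (camera adjusted p = 0.569), with the microRNA exporter XPO5 at -0.56.

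The lists with fewer than 5 measured members were not tested as lists. Huntingtin (HTT) fell by 0.34 as the called member of 2. Of the 2 measured fibroblast markers COL1A1 rose by 0.29. Of the 3 measured markers of kidney-derived packaging cells, CDH2, below detection on all control arrays, was higher (adjusted p = 6.64e-05). Adjusted over the list alone, the numbers of higher and lower members equalled those over all genes in 30 of the 34 lists. The integrated stress response then counted 10 higher and 9 lower, ribosomal proteins 7 lower, and the huntingtin and packaging-cell lists 2 lower each.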

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

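The tests of array brightness, of leukocytes and of the share of dividing cells were chosen only after the result was seen; the others were written down before their results were seen.

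In 7 of 224 groups of 4 arrays 1 array lay far from the other 3, against the 1 in 20 that chance gives. Nearly all of these groups are single genes, so that rate does not bear on a whole array. On shControl 1, SPINK1 stood at 5.38 against 4.84 to 4.93 on the other controls, SPP1 at 4.31 against 4.79 to 4.85, HSPB1 at 11.86 against 11.99 to 12.01 and RPL32 at 7.93 against 8.02 to 8.03. SPINK1 and SPP1 are near the detection limit in the controls. FJX1 was at 11.005 on shControl 4 against 11.15 to 11.16. Detected probes numbered 16476 on shControl 3 against 17265 to 17406, and 17191 on shZNF395 3 against 16834 to 16882. Each array 3 also had the highest mean correlation of its group with the other group. It was r = 0.9678 for shControl 3 and r = 0.9686 for shZNF395 3, below their means within the group (0.9948 and 0.9936). The cause was not tested. Without both arrays numbered 3, 4647 genes were called.

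Most tested genes differed between the groups. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real split, called as many as 4604 genes. The highest of the other splits called 0. Every other split mixes the groups, so the group difference enters its residual spread and lowers its calls. A share of 1 in 35 is also the smallest this test can give, so it cannot exclude chance. Because the labels do not say that replicates were separate cultures, a chance difference between cultures was not tested. With each array's log2 median raw signal as a covariate, limma called 3906 genes for the group and 0 for the covariate. The 3906 genes are 50.5% of those tested, only just above the bound set for this test. At most 36.8% of the probes were detected on an array, so the median probe lies at background and does not measure how bright the detected probes were. The test therefore cannot decide whether brightness contributes. Lentiviral delivery, selection and hairpin off-targets may differ between the groups, and no test here bears on them. A biological effect of lower ZNF395 therefore stays open beside them and beside brightness.

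Interferon and NF-kappaB genes were higher in shZNF395. Only 2 of 12 leukocyte markers (10 with a paired probe), CD14 and LAPTM5, were detected on all 4 shZNF395 arrays, and both also on all 4 shControl arrays, while PTPRC, TYROBP and ITGAM stayed below detection on all 8, which argues against leukocytes as the source. Interferon secreted by the cells in response to hairpin RNA may lie behind the rise, and cannot be told apart from an effect of lower ZNF395. Of 3 genes for IFNB1 and the IFNL family, 0 were detected on all shZNF395 arrays. Of the 13 interferon genes with a probe, 0 were detected on any of the 8 arrays. Brief or earlier production may still leave no trace at 48 h. Class I antigen presentation genes did not shift as a group relative to other genes (limma camera adjusted p = 0.499).

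Proliferation genes were lower in shZNF395. Of 10000 random lists matched on mean expression, 100% had a higher median than the 2 lists together, so genes of similar expression did not fall by as much. The mitosis median minus the replication median was -0.0427 (SE 0.0844), so the list medians fell by a similar factor. Single genes fell by unequal amounts, with an SD of 0.27 over the mitosis list and 0.22 over the replication list. Similar medians are a weak check, because lower expression per cell could give them too. A lower share of dividing cells therefore remains a hypothesis. Lower expression per cell stays open, since no cell counts were analysed here.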

How the results depend on the processing

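The counts over every detected probe, the fit without both arrays numbered 3, the fit with genes read by 2-probe entries and the medians of the authors' table were chosen after seeing the data. The genes changed numbered 4171 to 4602 when 1 array was left out, and ZNF395 stayed between -0.88 and -0.75 under every alternative run, with adjusted p of at most 0.000193. A limit of 1.5-fold left 1350 genes (852 higher, 498 lower), and adjusted p under 0.01 left 3610, both fewer by construction. Every detected probe gave 9512 (4356 higher, 5156 lower); why the balance turned was not tested. The replicate number as a block gave 4190 genes. Same-numbered arrays did not deviate together (correlations -0.11, 0.03, -0.44 and -0.12), and 0 of 8 arrays correlated best with their own number. No shift in the same direction by number was therefore seen. The arrays numbered 3, however, deviated in opposite directions (-0.44), and each correlated more with the other group than the rest of its group did. The cause of this was not tested, and whether same-numbered samples were handled together is not known. With the threshold unchanged, the part of the called genes still tested that kept call and direction ran from 90.3% with the replicate block to 4240 of 4241 genes with detection on all 8 arrays, and 2 genes reversed with the mean of probes. Cyclic loess gave 2711 higher and 1887 lower. Camera with an estimated correlation ended 4 calls: lysosome and autophagy (0.0514), oxidative stress (0.0514), hypoxia (0.0864) and epithelial (0.244). The ribosomal protein list passed with median scaling (0.00778), cyclic loess (0.0428), no filter (0.0149) and the mean of probes (0.0453). Without a filter the cholesterol (0.0311), matrix (0.0331) and metallothionein (0.0343) lists passed; the cause was not tested for these. Over the alternatives the genes picked by the naming rule kept direction and side of the threshold in 2130 comparisons and lost the call in 8, with 0 reversed: TARBP2 lost its call with the mean of its probes (0.14, adjusted p = 0.0834), and PECAM1 lost its call in 7 settings. Over all entries of the authors' deposited table, list medians moved by more than the spread between arrays in 25 cases and stayed within it in 4, and no list past the test changed sign. The authors' table could not stand in as values per array, and slide as a block was not run. Signal over background limits sizes: 133 called genes have only a bound.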

Other observations

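The grouping by symbol prefix and the genes named in this part were chosen after the values were seen; the tests of antigen presentation and of zinc finger genes were written down before their results were seen.

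Small nucleolar RNA genes (SNORD) had the smallest camera p of 87 families of genes that share a symbol prefix. Of 39 measured, 34 were lower and 4 higher, with a median log2 change of -0.66 (camera adjusted p = 2.4e-07, and adjusted p = 0.439 with an estimated correlation). The other small nucleolar RNA family, SNORA, did not pass, with 18 of 34 lower and 7 higher (camera adjusted p = 0.0938). Whether these probes read the mature small RNAs or longer transcripts that contain them was not tested. Genes named as small nucleolar RNA hosts (SNHG), which were not paired with the SNORD genes measured, had 7 of 11 lower (camera adjusted p = 0.0286). The nuclear pore genes (NUP) had 12 of 16 lower (camera adjusted p = 0.00437). The interleukin and interleukin receptor genes (IL) had 14 of 22 higher and 1 lower, at a median of 0.51 (camera adjusted p = 0.00059). With an estimated correlation 0 of the 11 families past the test pass, at adjusted p from 0.439 to 0.554, and 0.439 for each of SNORD, SNHG, NUP and IL.

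Of 12 measured antigen presentation genes, 7 were higher and 4 lower, at a median log2 change of 0.25. HLA-B (-0.62), HLA-F (-0.46) and HLA-G (-0.39) fell while HLA-E rose by 0.43. TAP1 (0.97), TAPBPL (0.55), IRF1 (0.55), TAPBP (0.45), PSMB10 (0.28) and PSME1 (0.22) rose and TAP2 fell by 0.38. Without the 2 genes shared with the interferon list, 5 of 10 were higher and 4 lower. The limma camera test of those genes gave an adjusted p = 0.918. Class I probes can read related HLA genes.

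Zinc finger genes were tested as a family because ZNF395 belongs to it. Of 233 measured ZNF genes other than ZNF395, 71 were higher and 54 lower, at a median of 0.02, and the family did not shift relative to other genes (camera adjusted p = 0.822).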
